A study of Mus musculus with 16 samples.

How the data were processed

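The deposited values, 1 file per infected library, were TPM per Ensembl transcript per the file headers, summing to 1000000 in each library, with no scaling between libraries stated. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and the mm10 build with no role for each, and the tool that made the TPM is not given in the sources used here. The design had assumed FPKM because Cufflinks is named; the files hold TPM, and every rule was applied to TPM in its place. Per the labels, total RNA was extracted with TriPure reagent from E14 ESC grown with LIF and inhibitors of MEK and GSK3, or from NPC made from them, and directional libraries were prepared from it.

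Each file listed 119215 transcripts, of which 116684 matched GENCODE M21 (GRCm38) by identifier without its version and 2531 did not, carrying 0.638 to 0.959 percent of the TPM of a library. The unmatched transcripts were left out. TPM were summed over the transcripts of a gene symbol, giving 35852 symbols, 38 of them shared by several gene identifiers. Long noncoding genes were mostly absent from the files, so a list of nuclear RNAs meant as a check of RNA quality had 0 measured members and no result. Libraries were scaled by median-of-ratios factors (0.907 to 1.17) from the 10785 genes above 1 TPM in all 8 libraries, and scaled TPM were used with a pseudocount of 1. Reads per library were estimated from the spacing of the lowest TPM values times effective length: in units of 1000000 they were 51.2, 35.1, 20.2 and 34.4 in ESC and 30.3, 15.1, 42.6 and 29.7 in NPC. The order is WT empty, KO empty, KO Auts2S and KO truncated. Between 65.9 and 74.6 percent of the low values lay within 0.1 of a whole number of such steps.

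Each label had 1 library at each stage. NPC were compared with ESC by limma 3.58.1 (lmFit, then eBayes with a trend) on log2 of scaled TPM plus 1, with the label as a block, over the 14731 genes with a mean of at least 1 scaled TPM. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Labels were compared over both stages by limma with an additive stage term, at an adjusted p under 0.05. This fit averages the stages and takes its spread from how far they disagree, so a list can be called from a difference at a single stage. Within a stage, labels were compared library against library with no p-value: a gene passed when the ratio of scaled TPM plus 1 was at least 2-fold and the higher TPM was at least 5. The planned requirement of separate confidence intervals was void because the files give no bounds. The median ratio of a list was placed among 10000 random lists of equal size drawn from 20 bins of mean expression with seed 1. Random lists were drawn gene by gene, so they lack the co-expression of a real list and the percentile measures no spread between cultures.

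The lists, 32 with 586 distinct genes, were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, each adjusted over the lists of a fit. Camera compares the members of a list with all other genes, and fry tests whether the members on balance move one way without that comparison. The number of members passing when adjusted over the list alone was counted as well.

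Reversal was measured across genes by correlating the difference of KO empty from WT empty with that of KO truncated from KO Auts2S, which share no library, and by the share of genes that passed the first difference and had the matching sign in the second, with exact Clopper-Pearson binomial intervals. The other pairings of the 4 libraries were computed in the same way. The extent of differentiation was the median log2 ratio of NPC to ESC in a label over genes called from the other 3 labels.

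Genes were named by rule, with Auts2 first. Between the stages these were the 10 largest changes each way with the same sign in all 4 labels. Within a stage they were the 8 largest differences each way for KO empty against WT empty and for KO Auts2S against KO empty in NPC, and the 4 largest in the other single-library comparisons. For reversal they were the 8 largest paired differences each way, and from each list up to 4 passing members. Predicted genes (Gm, Rik and LOC names), pseudogenes, small RNAs, histone genes and ribosomal protein genes were skipped. No gene qualified over both stages. In the report some lists have fewer or other passing members as examples, or more than 4, chosen after the values were seen.

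In a self-test with simulated libraries of known changes, the stage test recovered 75 of 100 genes at a log2 change of 1.5 and 98 of 100 at 3, with 14 of the unchanged genes called. The fit over both stages recovered 22 and 92 of 100, with 8 unchanged genes called. The size rule recovered 100 and 100, with 1 unchanged gene passing. Its simulated library was drawn from WT empty in NPC with counting noise alone and held no variation between cultures or libraries. That result thus does not bound false passes in the real comparisons. The change simulated for the fit over both stages was the same at each stage, and a change at a single stage was not simulated. A gene-level count of 0 over both stages thus leaves room for shared differences of 1.5 on the log2 scale. Differences at a single stage add to the spread of the fit, so the count does not bound their size.

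Alternatives were the deposited TPM without scaling, upper-quartile scaling, a pseudocount of 0.1, no filter or a mean of at least 5, eBayes without a trend, no block, leaving out libraries, adjusted p alone, other thresholds of the size rule, and the highest identifier of a repeated symbol. The 8 untreated samples were left out because they carried no values. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.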

Results

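Mouse E14 embryonic stem cells (ESC) and the neural progenitor cells (NPC) made from them were profiled by RNA sequencing in a study of Auts2 in neuronal differentiation. Transcript values were deposited for 8 libraries, 1 for each of 4 labels at each stage. The labels were wild-type cells with an empty lentiviral vector (WT empty), and Auts2 knockout cells with the empty vector (KO empty), an Auts2S vector (KO Auts2S) or a truncated Auts2S vector (KO truncated). The 8 untreated samples of the series carried no values and were not analysed here. Each library measured 12830 to 14503 genes at 1 TPM or more, and the step between its lowest values implied a depth of 15.1 to 51.2 (units of 1000000 reads). Levels below are scaled TPM, given in the order WT empty, KO empty, KO Auts2S and KO truncated unless another order is stated.

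Auts2, a long gene on the minus strand of chromosome 5 (131437333 to 132543344, GENCODE M21 on GRCm38), was not lowest in the libraries labelled KO. Its level in ESC was 5.11, 20.8, 15.3 and 16.7 TPM, so the library labelled KO empty held 4.07-fold the level of the library labelled WT empty. In NPC it was 33.8, 299, 366 and 44.6 TPM, that is 8.84-fold the WT empty level in the library labelled KO empty, 10.8-fold in the library labelled KO Auts2S and 1.32-fold in the library labelled KO truncated. A transcript with a retained intron, Auts2-219, carried 1.06 percent of the Auts2 TPM in the library labelled WT empty and 18.8 to 25.9 percent in the KO libraries in ESC. The shares were 2.19 percent against 19.2 to 27.0 percent in NPC. The coding transcript Auts2-209 had 14.5, 128, 160 and 19.6 TPM in NPC. In ESC the vectors added no visible excess over KO empty, with Auts2 at 0.735-fold in the library labelled KO Auts2S and 0.804-fold in the library labelled KO truncated. The place of the deletion is not in the labels, so the level of the whole gene cannot show whether functional Auts2 was lost. Every direction below is one between labelled libraries, not between known doses of Auts2.

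**Figure D1:**
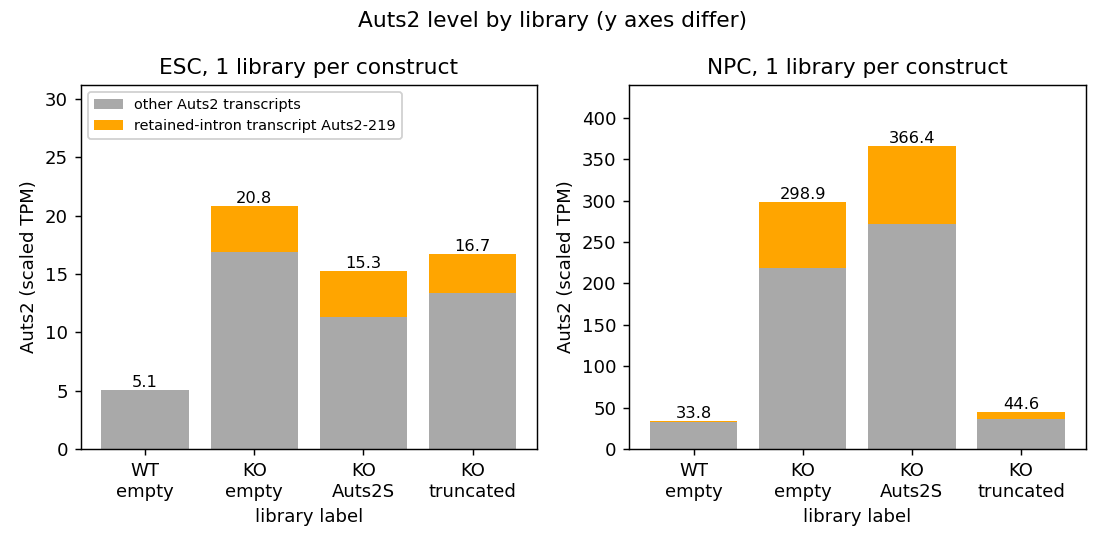
Auts2 in scaled TPM in the 8 libraries, with the part assigned to the retained-intron transcript Auts2-219 shown apart. The ESC and NPC panels have different axes.

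Differentiation from ESC to NPC lowered pluripotency genes and raised Hox and retinoid genes in the libraries of all 4 labels. Hoxa5 rose from 0.29, 1.06, 0.98 and 1.12 TPM to 189, 314, 296 and 364 TPM (log2 change 7.28, adjusted p = 7.43e-05, limma with the label as a block). Pou5f1, the core pluripotency factor, fell from 2008, 1317, 1509 and 1373 TPM to 7.55, 41.1, 25.5 and 2.54 TPM (log2 change -6.82, adjusted p = 0.000794). Of 14731 genes tested, 2279 rose and 2191 fell at least 2-fold with an adjusted p under 0.05. The balance turned with the scaling, at 2611 and 1916 without scaling and 2060 and 2500 with upper-quartile scaling. These p-values measure only the spread between these samples, in which the 4 labels stood in for replicates. Auts2 itself rose between the stages (log2 change 3.04, adjusted p = 0.00562).

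The largest rises were those of Ptn, a secreted growth factor of radial glia (log2 8.17, SE 0.33, adjusted p = 0.000229), the imprinted growth factor Igf2 (7.60, SE 0.46) and Hoxa5. The retinoic acid hydroxylase Cyp26b1 (6.89, SE 0.62) came next, before Hoxb3 (6.81), Hoxa4 (6.79), Nr2f1 (6.79), the collagen Col3a1 (6.75), the retinoic acid receptor Rarb (6.46) and Hoxb2 (6.46). The largest falls were those of Tdgf1, the Nodal co-receptor (-7.28, SE 0.26, adjusted p = 0.000229), the threonine dehydrogenase Tdh (-6.96) and Pou5f1. Zfp42 (-6.58), Fgf4 (-6.51), Nanog (-6.47), Trh (-6.46), Spp1 (-6.23), Pla2g1b (-6.20) and Triml2 (-6.12) followed. Nanog kept 33.0 TPM in the library labelled KO empty at the NPC stage and 15.0 TPM in KO Auts2S, against 3.29 TPM in WT empty and 1.80 TPM in KO truncated.

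Of 26 naive pluripotency genes 23 fell, Dppa5a (-5.99) and Nr5a2 (-4.61) among them, and 3 did not pass, including Sox2 (-2.61, adjusted p = 0.0535), which neural progenitors also use. The list moved down (median -4.69; camera adjusted p = 1.31e-13; fry adjusted p = 0.00454), with 25 of 26 members passing when adjusted over the list alone, and an adjusted p = 0.359 with an estimated correlation. Hox genes rose in 23 of 25 cases, for example Hoxa3 (6.23) and Hoxc5 (5.98), with none lower and 2 not passed. The median was 5.13 (camera adjusted p = 9.22e-13, fry adjusted p = 0.00454, 24 over the list alone; adjusted p = 0.359 with an estimated correlation). Retinoic acid response genes rose in 10 of 13 cases, with Dhrs3 (6.20), Cyp26a1 (6.16) and Crabp2 (5.13), while 1 fell and 2 did not pass (camera adjusted p = 3.02e-05, fry adjusted p = 0.00827, 12 over the list alone; adjusted p = 0.359 with an estimated correlation).

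Of 34 neural progenitor genes 17 rose, including Fabp7 (5.0, adjusted p = 0.0188), Cdh2 (4.31), Sox9 (4.19), Hes5 (4.09) and Irx3 (3.51). Nkx6-2 fell (-2.95) and 16 did not pass (camera adjusted p = 5.76e-05, fry adjusted p = 0.0616, 23 over the list alone; adjusted p = 0.663 with an estimated correlation). Postmitotic neuron genes rose in 11 of 32 cases, Lhx1 (4.72) and Nhlh2 (3.55) among them, and 21 did not pass (camera adjusted p = 0.000608, fry adjusted p = 0.217, 11 over the list alone; adjusted p = 0.663 with an estimated correlation). Synapse and axon genes split into 7 that rose, such as Cplx2 (3.50) and Dlg4 (3.42), 2 that fell and 14 not passed (camera adjusted p = 0.00944, fry adjusted p = 0.0616, 11 over the list alone; adjusted p = 0.663 with an estimated correlation). Notch response genes rose in 4 of 9 cases and 5 did not pass (camera adjusted p = 0.033, fry adjusted p = 0.0306, 4 over the list alone; adjusted p = 0.555 with an estimated correlation). Neural crest genes split 3 up, 2 down and 5 not passed around a median of -0.36 and a mean of 0.27 (camera adjusted p = 0.944, direction down; 7 over the list alone). Astroglia and oligodendrocyte genes gave 5 up, with Sparcl1 at 4.37, 3 down, with Apoe at -3.15, and 3 not passed (camera adjusted p = 0.325, fry adjusted p = 0.0306; 9 over the list alone).

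BMP genes changed in part. Of 18 BMP target genes 7 rose, with Msx1 (4.12), Hey1 (3.88), Id2 (3.80) and Id3 (3.62). Tfap2c (-2.33) and Smad7 (-1.33) fell, and 9 did not pass, Id1 among them (1.31, adjusted p = 0.0559). That list gave a camera adjusted p of 0.00968 and a fry adjusted p of 0.00885, with 10 members over the list alone, and adjusted p = 0.359 with an estimated correlation. Of 18 BMP pathway components 11 rose, for example Bmper (3.14) and Nbl1 (2.05), which code for extracellular regulators, and 7 did not pass (camera adjusted p = 0.000608, fry adjusted p = 0.00454, 12 over the list alone; adjusted p = 0.359 with an estimated correlation). Genes of the Auts2, Ski, Wdr68 and Cul4 proteins split into Auts2 and Cul4a (1.07) up, Cul4b (-1.92) down and 7 not passed (camera adjusted p = 0.795; 3 over the list alone). Polycomb partners of Auts2 split 2 up, with Yaf2 at 2.72, 2 down, with Fbrsl1 at -2.17, and 8 not passed (camera adjusted p = 0.711; 4 over the list alone).

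Genes of other germ layers moved too. Endoderm genes rose in 12 of 22 cases, with Plat at 5.23, and fell in 2, with 8 not passed (camera adjusted p = 0.00722, fry adjusted p = 0.0615, 15 over the list alone; adjusted p = 0.663 with an estimated correlation). Mesenchyme and fibroblast genes rose in 12 of 22 cases, Twist1 (4.33) and Col1a1 (3.45) among them, fell in 2 and did not pass in 8 (camera adjusted p = 0.000844, fry adjusted p = 0.00454, 15 over the list alone; adjusted p = 0.359 with an estimated correlation). Mesoderm and cardiac genes gave 9 up, 3 down and 9 not passed (camera adjusted p = 0.157; 12 over the list alone). Surface ectoderm and epithelium genes gave 6 up, with Krt18 at 2.96, 4 down, with Cdh1 at -4.20, and 4 not passed (camera adjusted p = 0.536; 11 over the list alone), and trophoblast genes gave 1 up, Krt7 at 2.45, 4 down and 3 not passed (camera adjusted p = 0.536, fry adjusted p = 0.0306, direction down; 5 over the list alone). Imprinted genes rose in 8 of 12 cases, with Igf2, Cdkn1c (5.78), Dlk1 (5.77) and Peg3 (4.45). Phlda2 fell (-2.63) and 3 did not pass (median 2.24, camera adjusted p = 0.00944, fry adjusted p = 0.00885, 10 over the list alone; adjusted p = 0.663 with an estimated correlation). Formative epiblast genes gave 1 up, Sall2 (2.37), 4 down, with Dnmt3l (-5.61) and Otx2 (-3.93), and 8 not passed (camera adjusted p = 0.227, fry adjusted p = 0.0306; 7 over the list alone).

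Camera at its preset correlation called lists of metabolism, cycle, germ cells and the p53 response down, but none of them at an estimated correlation. Hypoxia and glycolysis genes fell in 8 of 15 cases, with Slc2a3 at -4.68, rose in 1 and did not pass in 6 (camera adjusted p = 0.00175, fry adjusted p = 0.0177, 10 over the list alone; adjusted p = 0.639 with an estimated correlation). Germline genes fell in 8 of 10 cases, Sycp3 (-3.32) and Ddx4 (-2.50) among them, with 2 not passed (camera adjusted p = 0.0027, fry adjusted p = 0.00885, 8 over the list alone; adjusted p = 0.663 with an estimated correlation). Cell cycle genes fell in 5 of 24 cases, with Mcm5 at -1.55, rose in 1 and did not pass in 18 (camera adjusted p = 0.00408, fry adjusted p = 0.00773, 6 over the list alone; adjusted p = 0.359 with an estimated correlation). The p53 response fell in 4 of 14 cases, with Mdm2 at -1.68, and did not pass in 10 (camera adjusted p = 0.00722, fry adjusted p = 0.125, 4 over the list alone; adjusted p = 0.663 with an estimated correlation).

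The other lists had no call with camera; with fry, Nodal and interferon response genes had calls, both down. Nodal and TGF-beta response genes gave 3 up, with Tgfbi at 2.07, 5 down, with Nodal (-5.81) and Lefty2 (-5.44), and 1 not passed (camera adjusted p = 0.157, fry adjusted p = 0.018; 9 over the list alone). WNT response genes gave 3 up, with Nkd1 at 4.02, 3 down, with Cdx1 at -3.39, and 7 not passed (camera adjusted p = 0.956, direction up, with a median of -0.03 and a mean of 0.11; 6 over the list alone). FGF and ERK response genes gave 3 up, with Phlda1 at 2.13, 2 down, with Spry2 at -2.13, and 6 not passed (camera adjusted p = 0.536; 6 over the list alone). Hedgehog response genes gave 1 down and 7 not passed (camera adjusted p = 0.985, direction up, with a median of 0.31 and a mean of -0.02; 1 over the list alone). Interferon response genes gave 2 up, 3 down, with Oas1a at -3.93, and 9 not passed (camera adjusted p = 0.536, fry adjusted p = 0.00885; 3 over the list alone). Stress and unfolded protein genes gave Herpud1 up (1.80), 1 down and 13 not passed (camera adjusted p = 0.795; 1 over the list alone). Of 11 genes of the 2-cell-like state 0 passed, with a median of -0.61 and a mean of -0.62 (camera adjusted p = 0.325; 0 over the list alone).

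In NPC, many neural genes and 14 of 25 Hox genes were lower in the library labelled KO empty than in the library labelled WT empty. Hoxb9, a trunk Hox gene, stood at 669 TPM in WT empty and 3.56 TPM in KO empty (log2 difference -7.20), and the proneural factor Neurog1 at 118 and 0.37 TPM (-6.44). The dorsal spinal cord factors Msx3 (119 and 0.42 TPM, -6.39) and Zic1 (132 and 1.02 TPM, -6.04) were nearly as far apart, with Fez1 (164 and 1.31 TPM, -6.16) and Igfbpl1 (97.0 and 0.45 TPM, -6.08). In the other direction Grin2c stood at 1.10 and 129 TPM (5.96), the adhesion molecule Alcam at 4.11 and 238 TPM (5.55) and Asb4 at 1.20 and 84.8 TPM (5.28). The chemokine Cxcl12 (3.42 and 162 TPM, 5.21), the mesenchymal homeobox gene Hlx (1.53 and 81.4 TPM, 5.02) and Tmem72 (8.24 and 234 TPM, 4.67) followed. By the size rule, at least 2-fold with 5 TPM or more in the higher library, 1671 genes were higher and 1784 lower of 11636 eligible. Without scaling between libraries the split was 2598 higher and 1329 lower, and the median of all genes moved from 0.08 to 0.33. These differences stand between single libraries and have no replicate check. Auts2 lay higher in KO empty and the Y-linked Ddx3y, Eif2s3y and Uty lower (50.8 and 4.93 TPM summed), so no cause can be assigned to the genotype alone.

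Neuronal and progenitor genes were among the most shifted groups of that comparison. Of 34 neural progenitor genes 26 were lower and 2 higher, with 6 not passed (median -3.23). Fabp7 stood at 181 and 2.14 TPM, Hes5 at 130 and 1.25 TPM, Dll1 at 75.7 and 0.52 TPM, Pax6 at 72.9 and 2.01 TPM and Sox2 at 116 and 10.7 TPM. Lhx2, a forebrain and limb factor, was higher (2.72 and 91.8 TPM). Of 32 postmitotic neuron genes 26 were lower, including Tubb3 (329 and 7.12 TPM, -5.35), Cntn2 (63.6 and 0.94 TPM), Robo3 (95.7 and 1.73 TPM) and Elavl3 (60.4 and 0.93 TPM), 0 higher and 6 not passed (median -3.11). Notch response genes were lower in 6 of 9 cases and higher in 2, with 1 not passed (median -3.79). Each of these medians lay at percentile 0.0 of 10000 random lists of matched expression, which lack the co-expression of a real list. Hox genes were lower in 14 of 25 cases, with Hoxb8 at 252 and 5.68 TPM, higher in 1, Hoxd9, and not passed in 10, among them Hoxa5 (189 and 314 TPM) and Hoxa4 (136 and 226 TPM) (median -1.71). Retinoic acid response genes were lower in 6 of 13 cases, higher in 1 and not passed in 6, with Crabp2 at 568 and 40.03 TPM (median -0.71, percentile 0.23).

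BMP target genes were shifted the other way: 9 of 18 were higher, 3 lower and 6 not passed (median 1.18, percentile 99.99). Id1, the immediate target of BMP SMADs, stood at 34.0 and 144 TPM (2.05), Id3 at 259 and 626 TPM (1.27), and Smad6 at 6.79 and 23.0 TPM (1.62). Bambi stood at 2.79 and 20.4 TPM (2.5) and Dlx5 at 0.36 and 9.99 TPM (3.01). Id2 (0.95) did not pass, and the neural border genes Msx1 (-2.99), Tfap2a (-1.85) and Msx2 (-1.53) were lower. BMP pathway components split 5 higher, 5 lower and 8 not passed (median -0.01), with the ligand Bmp4 higher (11.6 and 42.3 TPM), Bmp7 lower (32.4 and 5.46 TPM) and the modulator Bmper higher (1.78 and 27.0 TPM). Genes of the Auts2, Ski, Wdr68 and Cul4 proteins gave 2 higher, Auts2 and Cul4b (13.7 and 34.3 TPM), and 8 not passed (median -0.06). Polycomb partners of Auts2 gave 2 higher, with 10 not passed (median -0.10).

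Mesoderm and imprinted genes were shifted up by their medians in the library labelled KO empty, though not all passed and some were lower. Of 21 mesoderm and cardiac genes 10 were higher, for example Hand2 (1.09 and 36.3 TPM), Foxc2 (6.30 and 43.0 TPM) and Tnni1 (6.5 and 36.6 TPM), 2 lower and 9 not passed (median 1.23, percentile 99.99). Endoderm genes gave 7 higher, with Gata4 (5.94 and 134 TPM) and Gata6 (3.98 and 111 TPM), 2 lower and 13 not passed (median 0.39, percentile 90.5). Mesenchyme genes gave 6 higher, with Twist1 (16.4 and 186 TPM) and Pdgfra (3.61 and 52.3 TPM), 3 lower and 13 not passed (median 0.29, percentile 75.6). Imprinted genes gave 7 higher, with Igf2 (571 and 4641 TPM), Dlk1 (43.0 and 197 TPM) and Peg3 (72.6 and 299 TPM), 1 lower and 4 not passed (median 1.66). Naive pluripotency genes gave 11 higher, 2 lower and 13 not passed (median 1.06). Genes of the 2-cell-like state gave 9 higher and 2 not passed (median 3.93), with Tmem92 at 1.30 and 42.6 TPM. The Zscan4 copies share reads and their split is uncertain. Stress genes gave 7 lower, Chac1 (-4.51), Psat1 (-3.89) and Asns (544 and 43.1 TPM) among them, and 8 not passed (median -0.99, percentile 0.02). Cell cycle genes gave 1 higher and 23 not passed (median -0.09). Synapse and axon genes gave 3 higher, 8 lower and 12 not passed (median -0.54, percentile 0.41). WNT response genes gave 2 higher, with Dkk1 at 3.08, 5 lower, with Axin2 at -1.74, and 6 not passed (median -0.98, percentile 0.17), and Nodal response genes 2 higher and 7 not passed (median 1.39, percentile 99.97). Among the largest differences, mt-Co2 and mt-Nd3 (higher in KO empty) share sequence with nuclear copies and Pgk1-rs7 (lower) is itself a copy of Pgk1. Their differences are uncertain, as is that of the short unnamed gene AC125203.1 (lower).

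In NPC, most neural progenitor and neuron genes were higher in the library labelled KO Auts2S than in the library labelled KO empty. Msx3 reached 227 TPM against 0.42 TPM in KO empty (log2 difference 7.32), Hoxb9 583 TPM (7.0), Fabp7 371 TPM (6.89) and Igfbpl1 127 TPM (6.46). Neurog1 stood at 107 TPM (6.30), Tubb3 at 507 TPM (5.97), Zic1 at 124 TPM (5.96) and Olig3 at 69.7 TPM (5.92). Lower than in KO empty were Grin2c at 0.28 TPM (-6.67), Alcam at 2.39 TPM (-6.14), Hlx at 0.22 TPM (-6.08) and Cxcl12 at 1.71 TPM (-5.91). Gata4 was at 1.29 TPM (-5.88), Gata6 at 0.95 TPM (-5.84), Asb4 at 0.53 TPM (-5.81) and the lateral mesoderm factor Foxf1 at 0.08 TPM (-5.55). Against KO empty, 1170 genes were higher and 1474 lower of 11386. Neural progenitor genes gave 25 higher, 2 lower and 7 not passed (median 3.22), and postmitotic neuron genes 27 higher and 5 not passed (median 3.33). Hox genes gave 14 higher, 1 lower and 10 not passed (median 1.81), and mesoderm and cardiac genes 1 higher, 11 lower and 9 not passed (median -1.66). Among BMP targets 3 were higher, with Msx1 at 3.76, 12 lower, with Bambi at -3.21, and 3 did not pass (median -1.23). This comparison shares the single KO empty library with that of KO empty and WT empty, so genes extreme in KO empty reverse in part by construction, and how much of the reversal exceeds that was not tested here. Auts2 differed by only 1.23-fold between these NPC libraries, so the contrast is one of labels with similar total Auts2 RNA. That total does not give the dose of functional Auts2.

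The library labelled KO truncated had most neural genes at levels that did not pass the size rule against KO empty, and its largest differences from KO empty were in globin genes. Against KO empty, the embryonic globin gene Hbb-y stood at 1095 and 0.17 TPM (9.87). Hbb-bh1 stood at 564 TPM, the embryonic alpha-like globin gene Hba-x at 423 TPM and Hbb-bh0, which shares reads with other globin genes, at 626 TPM. These 3 were listed at 0 in KO empty and KO Auts2S. Lower were Zscan4f (83.5 and 1.15 TPM, -5.29) and Tmem72 (234 and 5.91 TPM, -5.09), with the short unnamed genes AC123659.1 and AC127331.6, whose values are uncertain. Of 11048 eligible genes 826 were higher and 1435 lower, or 460 and 2214 without scaling, where the median of all genes moved from -0.04 to -0.26. Neural progenitor genes passed in 2 higher and 3 lower cases of 34 (median 0.46, percentile 100). Postmitotic neuron genes passed in 4 higher of 32 (median 0.18, percentile 99.3), with the motor neuron factor Lhx3 at 36.0 and 0.36 TPM, and Hox genes in 8 higher of 25 (median 0.21). Surface ectoderm and epithelium genes gave 10 higher, with Krt19 at 154 and 43.2 TPM, and 4 not passed (median 1.44). Hypoxia and glycolysis genes gave 7 higher and 8 not passed (median 1.09), and endoderm genes 8 higher, 1 lower and 13 not passed (median 0.77). Genes of the 2-cell-like state gave 9 lower and 2 not passed (median -3.94). BMP targets gave 1 higher, 3 lower and 14 not passed (median -0.07, percentile 54.8).

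Between the libraries labelled KO Auts2S and KO truncated in NPC, Msx3 (227 and 2.58 TPM, 5.99), Fabp7 (371 and 6.40 TPM, 5.65) and Robo3 (137 and 2.18 TPM, 5.44) were higher in KO Auts2S. The short unnamed gene AC123659.1, uncertain for its length, was higher there too, and Hbb-y (-10.10) led the genes higher in KO truncated. In all, 1058 genes were higher and 879 lower of 11090, or 1439 and 701 without scaling, where the median of all genes moved from 0.04 to 0.22. Neural progenitor genes gave 26 higher, 1 lower and 7 not passed (median 2.96), and postmitotic neuron genes 26 higher, 1 lower and 5 not passed (median 3.32). Surface ectoderm and epithelium genes gave 12 lower and 2 not passed (median -2.37), and endoderm genes 2 higher, 17 lower and 3 not passed (median -1.65). Mesoderm and cardiac genes gave 1 higher, 12 lower, with Tnni1 at -6.01, and 8 not passed (median -1.75). BMP targets gave 4 higher, 6 lower, with Bambi at -4.14, and 8 not passed (median -0.79). Auts2 was 8.21-fold higher in the library labelled KO Auts2S. KO empty had a similar excess over KO truncated (6.69-fold) with the neural genes low. Total Auts2 RNA and neural genes thus did not go together across the 4 libraries, which leaves the dose of functional Auts2 unknown.

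The genes with the largest paired differences in NPC were neural on the side lower in KO empty (Msx3, Fabp7, Zic1, Robo3, Tubb3, Igfbpl1, Hes5 and Elavl3) and mixed on the other, where the mesoderm and endoderm factors Gata6, Hlx and Gata4 stood with Asb4, Alcam, Cxcl12, Tac2 and Gli1. Elavl3 stood at 60.4, 0.93, 67.9 and 1.33 TPM, and Hes5 at 130, 1.25, 130 and 3.35 TPM. The neuropeptide gene Tac2 had 0.29, 28.7, 0.08 and 17.0 TPM, and the Hedgehog effector Gli1 4.97, 107, 1.91 and 44.7 TPM. Of the 1784 genes lower in KO empty, 1224 were higher in KO Auts2S than in KO truncated (68.6 percent, exact Clopper-Pearson binomial interval 66.4 to 70.8), 587 of them by the size rule. Of the 1671 genes higher in KO empty, 998 were lower in KO Auts2S than in KO truncated (59.7 percent, 57.3 to 62.1), 405 by the size rule, and without scaling, which shifts all genes, this share was 48.6 percent. The intervals cover counting error only. Across 14731 genes the difference of KO empty from WT empty correlated with that of KO truncated from KO Auts2S (Pearson 0.318, Spearman 0.244), although genes are not independent replicates. The difference of KO truncated from WT empty with that of KO empty from KO Auts2S, which sets the same libraries against each other, gave Pearson 0.397. That of KO Auts2S from WT empty with that of KO truncated from KO empty gave -0.106.

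**Figure D2:**
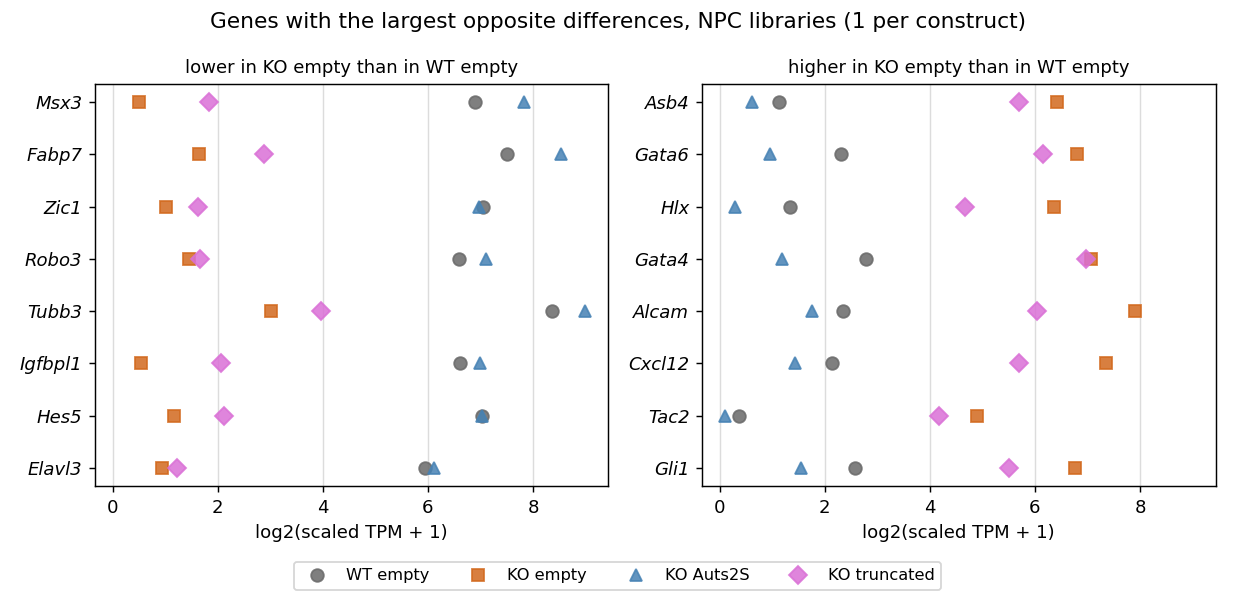
Levels of the 8 genes in each direction with the largest paired differences in the NPC libraries, 1 library per label.

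**Figure D3:**
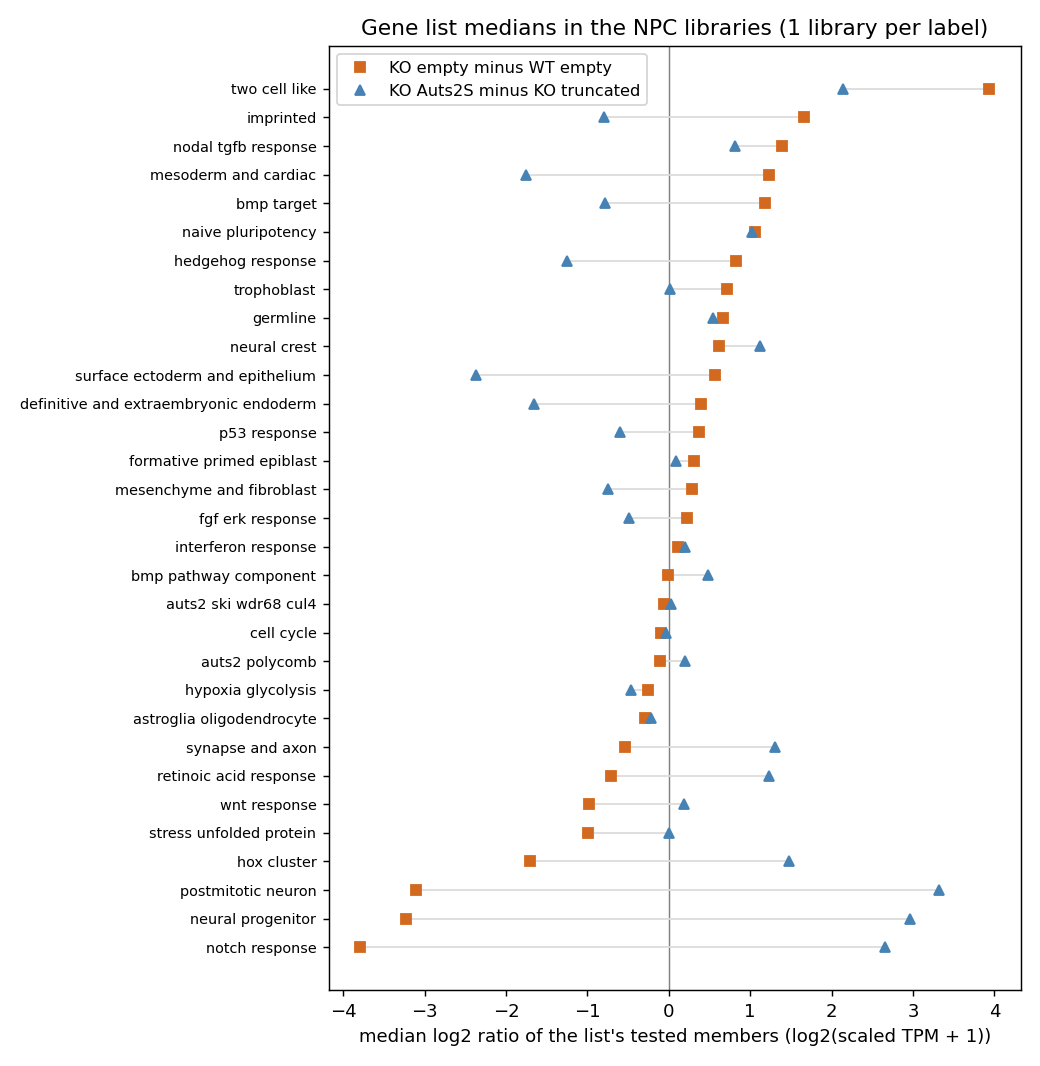
Median log2 ratio of each gene list between KO empty and WT empty, and between KO Auts2S and KO truncated, in NPC.

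Relative to WT empty, the 1784 genes lower in KO empty had medians of -1.76 in KO empty, -0.51 in KO Auts2S and -1.51 in KO truncated, and the 1671 genes higher in KO empty 1.59, 0.29 and 0.62. These genes were selected against the same WT empty library, which sets the KO empty values and pulls the others the same way. Over whole profiles the NPC libraries KO empty and KO truncated correlated at 0.916 and WT empty and KO Auts2S at 0.908. KO Auts2S and KO truncated also reached 0.908 and WT empty and KO empty 0.811. Over genes called from the other 3 labels, the median stage change of genes up was 1.86, 1.60, 1.73 and 1.47, against 1.80, 1.84, 1.92 and 1.83 in the libraries behind each call. For genes down it was -1.62, -1.72, -1.95 and -1.77, against -1.84, -1.79, -1.88 and -1.81. Each label has its own set of genes, and no difference in extent was tested.

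In ESC, 10 of 14 p53 response genes and 6 of 15 hypoxia and glycolysis genes were higher in the library labelled KO empty than in WT empty. Ddit4, a stress-induced inhibitor of mTORC1, stood at 13.6 and 249 TPM (4.10), and Mst1 at 0.67 and 22.5 TPM (3.81). The epoxide hydrolase Ephx1 stood at 3.06 and 52.9 TPM (3.73) and the immediate early gene Egr1 at 0.68 and 21.2 TPM (3.72). The Y-linked Ddx3y (-3.06) and Eif2s3y (-2.91) and the ligand Bmp4 (79.3 and 15.4 TPM, -2.29) were lower, as was the short unnamed gene AC123659.1. Of 10610 eligible genes 839 were higher and 195 lower, or 723 and 307 with upper-quartile scaling, and without scaling the median of all genes moved from 0.04 to 0.17. The p53 response gave 10 higher and 4 not passed (median 1.57), with Mdm2 at 57.7 and 269 TPM, Trp53inp1 at 35.4 and 191 TPM, Perp (2.99) and Cdkn1a (95.6 and 195 TPM). Hypoxia and glycolysis genes gave 6 higher, with Vegfa (2.79) and Bnip3 (2.22), and 9 not passed (median 0.55). Genes of the 2-cell-like state gave 7 higher and 4 not passed (median 1.86), and BMP targets 4 higher, with Id1 at 24.98 and 89.0 TPM, and 14 not passed (median 0.36, percentile 94.8). Formative epiblast genes gave 1 higher, 5 lower and 7 not passed (median -0.33). Neural progenitor genes gave 2 higher, 1 lower and 31 not passed (median 0.11), and Hox genes passed in 0 of 25 cases. The excess of Auts2 in the library labelled KO empty (4.07-fold) and the low Y-linked sum (55.0 TPM in WT empty, 5.12 TPM in KO empty) bound this contrast too.

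Against KO empty in ESC, Trh, Ptgs1 and several ERK-responsive genes were lower in both rescue libraries. Trh stood at 579, 45.3 and 36.0 TPM in KO empty, KO Auts2S and KO truncated (log2 differences -3.65 and -3.97). Etv4, a transcription factor induced by FGF signalling, stood at 40.7, 4.50 and 3.65 TPM (-2.92 and -3.16). The feedback inhibitor Spry4 had 7.72, 0.23 and 0.06 TPM (-2.82 and -3.04) and Ptgs1 10.0, 0.75 and 0.35 TPM (-2.66 and -3.03). Higher in both were Eif4e1b (0.51, 7.14 and 7.44 TPM) and Elobl (3.88, 20.5 and 19.6 TPM), with Irf5 among the 4 largest in KO Auts2S (2.08) and Stra8 (2.38) and Aurkc (2.28) in KO truncated. FGF and ERK response genes gave 6 lower and 5 not passed in KO Auts2S (median -1.07) and 5 lower and 6 not passed in KO truncated (median -0.85), each with percentile 0.0. KO Auts2S had 167 genes higher and 252 lower of 10652 (122 and 322 without scaling, where the median of all genes moved from -0.02 to -0.12). KO truncated had 109 higher and 157 lower of 10606 (90 and 209 without scaling). Both comparisons share the single KO empty library, so their likeness is expected from it in part, and Auts2 was not higher in either rescue library. The ESC were grown with inhibitors of MEK and GSK3. With 1 library per label, a difference between cultures cannot be told from one between vectors.

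KO Auts2S and KO truncated were close in ESC, with 94 genes higher and 36 lower in KO Auts2S of 10403. Sugct stood at 6.06 and 0.44 TPM (2.29). Ndufa4l2 (12.8 and 35.4 TPM, -1.40), Pagr1a (6.19 and 17.0 TPM, -1.33) and Lrrk2 (2.24 and 6.31 TPM, -1.17) were lower in KO Auts2S, apart from the uncertain AC123659.1, AC119957.1 and AC127331.8, which are short and unnamed, and Plac9b, which has a close copy. Of the 195 genes lower in KO empty than in WT empty, 105 were higher in KO Auts2S than in KO truncated (53.8 percent, exact interval 46.6 to 61.0; 44.2 percent without scaling), 3 of them by the size rule. Of the 839 genes higher in KO empty, 604 were lower in KO Auts2S (72.0 percent, 68.8 to 75.01), 13 by the size rule. The correlation across genes was 0.136 (Spearman 0.212). The difference of KO Auts2S from WT empty with that of KO truncated from KO empty gave 0.213, and that of KO truncated from WT empty with that of KO empty from KO Auts2S gave -0.075.

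Differences between KO empty and WT empty were shared by the stages more often than independent draws would give. Among 9572 genes eligible at both stages, 196 were higher in both (65.1 expected from 1095 in NPC and 569 in ESC) and 55 lower in both (16.1 expected from 1093 and 141). Another 86 passed in opposite directions, a count for which no expectation was computed, so it does not show that opposite differences were rare. The Pearson correlation of the differences across genes was 0.155 (Spearman 0.160). Auts2 itself, higher in the library labelled KO empty at each stage, belongs to the shared set.

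With both stages in a single fit and the stage as a block, the gene-level test with limma called nothing. It gave 0 genes for KO empty against WT empty (1340 at unadjusted p < 0.05, smallest adjusted p 0.539) and 0 for KO Auts2S against KO empty (360, 0.930). It gave 0 for KO truncated against KO empty (253, 0.997) and 0 for KO Auts2S against KO truncated (82, 1.0). The first count moved from 0 without the library labelled WT empty in ESC, and the last without the library labelled KO Auts2S in NPC. In each case a label was left with a single library and the spread came from the other labels, so these counts are not read. Camera at its preset correlation called lists in each comparison, but fry called none, with smallest adjusted p of 0.442, 0.175, 0.645 and 0.734 in the order above. The fit averages the stages, so a list may be called from a difference at a single stage. For KO empty against WT empty, camera had postmitotic neuron genes (adjusted p = 2.53e-07), neural progenitor genes (0.000127) and Hox genes (0.0485) down, with adjusted p = 0.754 or more with an estimated correlation. The NPC pair carried these: the medians were -3.11, -3.23 and -1.71 in NPC but -0.02, 0.11 and 0.22 in ESC. The 2-cell-like (8.16e-07), germline (0.000968), p53 response (0.0115), BMP target (0.0123), epithelium (0.0304) and naive pluripotency genes (0.0455) were called up, each with adjusted p = 0.754 or more with an estimated correlation. Naive pluripotency genes had opposite signs at the stages (median 1.06 in NPC, -0.24 in ESC, percentile 1.61), and the p53 response was larger in ESC (0.37 in NPC, 1.57 in ESC). Of 11 genes of the 2-cell-like state 8 passed when adjusted over the list alone, with 1 of 14 in the p53 response and 0 in every other list. The 2-cell-like genes had an estimated correlation of 0.965 with each other, so these 8 are not independent.

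For KO Auts2S against KO empty, camera called postmitotic neuron (2.10e-11), neural progenitor (6.06e-09), Hox (3.20e-05), retinoic acid response (0.00621) and cell cycle genes (0.0374) up. It called mesoderm (0.000146), FGF and ERK response (0.00675), epithelium (0.0117), BMP target (0.0182), 2-cell-like (0.0374), imprinted (0.0401), endoderm (0.0451) and Nodal response genes (0.0451) down, each with adjusted p = 0.654 or more with an estimated correlation. In ESC the medians of these lists lay between -0.46 and 0.12, apart from FGF and ERK response genes (-1.07, against -0.21 in NPC). KO truncated against KO empty had endoderm (0.00405), cell cycle (0.00405) and epithelium genes (0.00901) up and 2-cell-like (4.66e-06), naive pluripotency (0.000954) and germline genes (0.00405) down, each with adjusted p = 0.974 or more with an estimated correlation. Epithelium (1.44 in NPC, -0.41 in ESC), 2-cell-like (-3.94 and 0.33) and naive pluripotency genes (-1.10 and 0.21) were among those with medians of opposite sign in ESC. KO Auts2S against KO truncated had postmitotic neuron (2.66e-13), neural progenitor (2.12e-12), naive pluripotency (8.64e-05), synapse and axon (0.000399), 2-cell-like (0.00134) and Hox genes (0.00151) up, with adjusted p = 0.489 or more with an estimated correlation. The fit had epithelium (3.67e-11), endoderm (8.38e-11), mesoderm (1.85e-07), hypoxia (0.000406), imprinted (0.00161), p53 response (0.00182) and BMP target genes (0.0307) down, each with adjusted p = 0.489 or more with an estimated correlation. In ESC the medians of the lists called there lay between -0.38 and 0.07. With 1 library per label and stage, and Auts2 levels that do not follow the labels, these calls describe the libraries and cannot be carried to the constructs.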

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

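Of the checks in this part, only the splits of the stage test had been written before its result was seen; all other checks were chosen after the values were known. Values far from the other 3 libraries of a stage were sought with Dixon's test in 78 groups of 4 libraries, where about 5.0 percent would stand out by chance, and 6 did. Lists with opposite medians at the stages, each beyond the central 95 percent of random lists, numbered 13 of 124 pairs, and the difference between the stages was not tested.

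The first pattern was the loss of neural transcripts from the NPC libraries labelled KO empty and KO truncated, with Hoxb9 at 3.56 and 19.8 TPM against 669 TPM in WT empty and 583 TPM in KO Auts2S. Undifferentiated cells left in the cultures are argued against, since the naive pluripotency list kept a median of at most 5.05 percent of its ESC level in either library. A KO Auts2S library made mostly of WT cells is argued against too, because its Y-linked sum was 6.17 percent of that of WT empty. Rescue by the Auts2S vector and not by the truncated vector would fit the labels. With 1 library each, though, the labelled pairing has a chance of 33.3 percent among the 3 possible pairings. The correlation of the differences was 0.318, and 0.235 with a pseudocount of 0.1. Whether culture, clone or vector made the difference stays open, and it may be any of them.

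The second pattern was the high Auts2 level of the NPC libraries labelled KO empty and KO Auts2S (299 and 366 TPM). In KO empty, whose vector is empty by its label, transcripts of an Auts2S insert cannot be the source unless the label is wrong. In KO Auts2S, whether transcripts of the vector are the main source cannot be told. A coding insert holds no intron, and the retained-intron transcript Auts2-219 was 11.0-fold higher in KO Auts2S than in KO truncated. But Auts2-219 is a single unbroken stretch of 1780 bases, and whether it shares exon sequence with an insert was not checked. The coding transcript Auts2-209 was higher too (159.77 and 19.65 TPM). An exchange of the labels KO empty and KO truncated in NPC is left open by their Auts2 fold of 6.69 alone, since Auts2 in ESC showed no vector excess by which to tell them apart. Whether the truncated vector would then be the source cannot be told either, since the same limit holds for Auts2-219, at 80.6 and 8.57 TPM in these libraries. The higher level of Auts2-219 in all 3 KO labels at each stage leaves open that the altered locus itself makes more of this transcript.

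The third pattern was the low level of some mitochondrial transcripts in the NPC library labelled WT empty, with mt-Co2 at 140 TPM. Reads shared with nuclear copies would likely explain it: with the copies Gm28661, Gm28437 and Gm10925 added, mt-Co2, mt-Co3 and mt-Atp6 reached at least 0.931 of the lowest other NPC library, and mt-Nd3, outside that check, had 1453.8 TPM with its copy Gm28438 against 2022.2 TPM. Transcripts without such a copy had a median ratio of 1.23 to the lowest other library, KO Auts2S, which argues against fewer mitochondrial transcripts than in that library alone. Against KO empty and KO truncated most of these transcripts were lower in WT empty, and the question stays open there. For example, mt-Nd1 stood at 1340.6 TPM in WT empty against 5583.5 and 2866.0 TPM. The transcripts mt-Co1, mt-Cytb, mt-Nd2, mt-Nd5 and mt-Nd6 were also lower than in both. Only mt-Atp8 was higher than in both (13836.6 TPM against 10349.6 and 7413.3 TPM), and mt-Nd4l lay between them. The copy Gm28661 also took reads in KO Auts2S and KO truncated (936.2 and 876.5 TPM), and why it took most of them in WT empty was not tested.

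Between the stages, 1 of 35 splits of the libraries into 4 and 4, the real split, called as many genes, and the highest count of any other split was 1. The Y-linked genes Ddx3y, Eif2s3y and Uty summed to 55.0 TPM in WT empty in ESC and to 50.8 TPM in WT empty in NPC, each far above the other 3 libraries. Among list medians in ESC, KO empty stood apart for formative epiblast genes (4.00 on the log2 scale), mesoderm and cardiac genes (1.01) and Nodal response genes (4.11), and WT empty for postmitotic neuron genes (0.81). These are medians of levels. Medians of gene-wise differences did not set KO empty apart for formative epiblast genes. They were -0.33 for KO empty against WT empty, and -0.31 and -0.30 for KO Auts2S and KO truncated against KO empty. For mesoderm and cardiac genes they were 0.01, -0.05 and 0.005.

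Naive pluripotency genes had medians in NPC and ESC of 1.06 and -0.24 for KO empty against WT empty, -0.56 and 0.24 for KO Auts2S against KO empty, and -1.10 and 0.21 for KO truncated against KO empty. WNT response genes had 1.13 and -0.52 for KO Auts2S against KO empty and 0.86 and -0.35 for KO truncated against KO empty. For KO truncated against KO empty, epithelium genes had 1.44 and -0.41, p53 response genes 0.82 and -0.35, stress genes 0.50 and -0.44, hypoxia and glycolysis genes 1.09 and -0.14, and genes of the 2-cell-like state -3.94 and 0.33. For KO Auts2S against KO truncated, retinoic acid response genes had 1.23 and -0.12, FGF and ERK response genes -0.49 and 0.11, and genes of the 2-cell-like state 2.14 and -0.38.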

How the results depend on the processing

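By replicate number, no paired analysis was possible because each label had a single library at each stage. The stage test paired the libraries by label, as a block, and called 4498 genes without it. The stage count of 4470 genes ranged from 3216 to 4835 over the alternatives that kept both calling thresholds (3563 to 4059 without a label). By adjusted p alone it was 6059. Over both stages, 0 genes stayed 0 under every scaling, pseudocount and filter. Leaving out the library labelled WT empty in ESC moved the count from 0 for KO empty against WT empty. Leaving out KO Auts2S in NPC moved it for KO Auts2S against KO truncated. A label left with a single library is fitted exactly and adds nothing to the spread, which then comes from the other labels, so these counts are not given. No other omission moved a count from 0. In a comparison added after the data were seen, the mean of the 3 KO labels against WT empty called 0 genes (1020 at unadjusted p < 0.05, smallest adjusted p 0.294, for Eif2s3y).

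In the order KO empty against WT empty, KO Auts2S against KO empty, KO truncated against KO empty and KO Auts2S against KO truncated, the main counts of the size rule were 3455, 2644, 2261 and 1937 in NPC and 1034, 419, 266 and 130 in ESC. At 1.5-fold they were 5906, 4961, 4778 and 3609 in NPC and 2556, 1278, 963 and 320 in ESC, and with a higher TPM of at least 1 they were 1715, 804, 504 and 387 in ESC. The looser thresholds raise them by construction.

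The correlation behind reversal was 0.318 in NPC, 0.315 without scaling and 0.319 with upper-quartile scaling, and 0.136, 0.136 and 0.139 in ESC. Scaling shifts the log2 differences of all genes nearly alike and a shift leaves a correlation unchanged, so this likeness is largely by construction. The shares of signs did depend on scaling, as a shift of all genes moves them by construction (median of KO Auts2S against KO truncated 0.04 in NPC, 0.22 without scaling). In NPC the share of genes lower in KO empty with KO Auts2S above KO truncated moved from 68.6 percent to 75.5 without scaling and 64.1 with upper-quartile scaling, and the share of genes higher in KO empty with KO Auts2S below moved from 59.7 to 48.6, past an even split, and 62.7. In ESC these shares moved from 53.8 to 44.2, past an even split, and from 72.0 to 76.6 without scaling. The correlation moved to 0.235 in NPC with a pseudocount of 0.1 and to 0.112 in ESC with a mean of at least 5.

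The extent of differentiation moved with a pseudocount of 0.1 to 2.36, 1.91, 2.03 and 1.77 for genes up and -2.21, -2.04, -2.39 and -2.12 for genes down, in the order WT empty, KO empty, KO Auts2S and KO truncated. For KO truncated it was 1.30 and -1.99 without scaling, and -1.59 for genes down with upper-quartile scaling. List medians in NPC at a pseudocount of 0.1, added after the data were seen, were -4.61 and -3.89 for neural progenitor and neuron genes in KO empty against WT empty, and 3.65, 4.30 and -2.48 for neural progenitor, neuron and mesoderm genes in KO Auts2S against KO truncated. Also added afterwards, thinning the estimated reads to those of the NPC library labelled KO empty left 26 of 34 neural progenitor and 26 of 32 neuron genes passing in both comparisons. A counting interval was not used as a main rule, and the alternative without an interval criterion was void because the files used here give no bounds.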

Other observations

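The groupings in this part, and the genes Emcn, Cldn5, Tie1, Cdh5, Wt1, Pecam1, Uchl5 and Ddit4l, were chosen after the values were seen; the other genes were named by rule or belong to the lists. Every comparison is of single libraries. Beside the globin genes, 4 genes known from endothelium were highest in the NPC library labelled KO truncated: Emcn at 5.53, 2.01, 1.60 and 17.6 TPM, the tight junction gene Cldn5 at 6.17, 2.26, 1.93 and 18.9 TPM, Tie1 at 3.90, 4.31, 0.77 and 10.9 TPM and Cdh5 at 3.72, 3.55, 2.30 and 9.67 TPM. In WT empty Hbb-y, Hbb-bh1 and Hba-x were at 11.4, 12.9 and 16.1 TPM. Wt1, a gene of the embryonic kidney and mesothelium, stood at 12.0, 106, 4.04 and 137 TPM, along with Gata4 (5.94, 134, 1.29 and 125 TPM) and Foxf1 (2.31, 49.7, 0.08 and 50.5 TPM), which belong to lateral and splanchnic mesoderm. Pecam1, also an endothelial gene, was highest in WT empty, at 84.7, 38.9, 5.13 and 10.8 TPM.

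In ESC, the ERK-responsive genes Etv4 and Spry4, and Trh, stood in descending order through the libraries: Etv4 was at 119, 40.7, 4.50 and 3.65 TPM, Spry4 at 26.8, 7.72, 0.23 and 0.06 TPM and Trh at 871, 579, 45.3 and 36.0 TPM. Their lowest values were in both libraries with a rescue vector, whatever its insert. The ESC were grown with an inhibitor of MEK, and differences between cultures and between vectors were not told apart. The FGF and ERK list as a whole did not share the first step, with 3 higher, 2 lower and 6 not passed in KO empty against WT empty, and Egr1 was higher there (0.68, 21.2, 2.95 and 2.64 TPM). Uchl5 was lower in all 3 KO labels at both stages, at 347, 162, 153 and 149 TPM in ESC and 307, 91.3, 87.9 and 81.2 TPM in NPC, and Ddit4l was higher in all 3, at 4.81, 51.0, 22.1 and 17.1 TPM in ESC and 2.22, 16.7, 6.29 and 8.72 TPM in NPC.

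A change of lineage and a delay were not told apart as sources of the neural and mesodermal contrast. Gata4 and Wt1 were high in KO empty and KO truncated. The naive pluripotency list kept a median of 5.05 and 0.80 percent of its ESC level there, against 1.12 percent in WT empty. A delay past the naive state would leave these genes low too. Formative epiblast genes in NPC gave 1 higher and 12 not passed of 13 for KO empty against WT empty (median 0.31, percentile 75.4). For KO truncated against KO empty they gave 2 higher, 1 lower and 10 not passed (median 0). These medians showed no clear shift towards a formative state, and a delay at a later state was not tested. The BMP target list split along with the neural and mesodermal genes by its medians (1.18 for KO empty against WT empty and -0.79 for KO Auts2S against KO truncated), though not in every gene. Id1 was at 34.0, 144, 52.8 and 170 TPM and Bambi at 2.79, 20.4, 1.32 and 39.9 TPM, high where neural genes were low, but Msx1 was at 41.9, 4.40, 72.2 and 27.1 TPM. Higher BMP signalling in the libraries with few neural transcripts could be read from Id1, Id3 and Bambi, yet the same target genes are used by mesoderm, and 33.3 percent, the chance of the labelled pairing, bounds any claim about the vectors. BMP signalling and a larger share of mesoderm cells were not told apart here.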
